A study of Mus musculus with 15 samples.

How the data were processed

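Total RNA of leukemia cells from mouse spleens was extracted with a Qiagen RNeasy kit, amplified with a MessageAmp III kit and labelled with biotin, per the labels' protocols, and hybridised to Affymetrix Mouse Genome 430 2.0 arrays. The deposited table holds 1 intensity value per probe set and array, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of each set. Its version and settings are not given in the sources used here. The deposited intensities lie on a linear scale, with medians of 149.99 to 156.53 and no value at or below 0, so log2 of each value was taken before any test. Because RMA forces similar distributions on all arrays, a change of most genes in one direction would not be visible in these values.

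Genes were named through the platform annotation supplied with the values. Of 45101 probe sets, 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were controls. Of the 34945, 34741 had a gene identifier in the RefSeq table of assembly GRCm38.p6, which changed 0 symbols. Each of 18193 genes was represented by its probe set with the highest mean over all 15 arrays, and 9010 genes had more than 1 probe set. Probe sets with several or no names were left out of the main tests. No filter on dim genes was used. Every value column was used.

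Groups came from the sample titles: RAS-ON at 0 h (5 arrays) and RAS-OFF at 48, 60, 72, 84 and 96 h (2 arrays each). The labels call these replicates without saying that each came from its own animal, so p-values measure the spread between these samples, which may in part be technical. No scan date or batch is given in the labels. Within groups the arrays correlated at 0.990 to 0.998, and no pair of arrays was identical. The RAS-ON arrays fell into 2 sets: the SD of the log2 difference was 0.153 to 0.228 among arrays 1 to 3, 0.165 between arrays 4 and 5, and 0.250 to 0.348 between the sets.

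Genes were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, 1 shared estimate of the spread per gene, default eBayes and two-sided tests. P-values were adjusted by Benjamini-Hochberg over all 18193 genes, and an adjusted p below 0.05 counted as called. The contrasts were the mean of the 5 RAS-OFF groups minus RAS-ON, each RAS-OFF time minus RAS-ON, and the least-squares slope of the 5 RAS-OFF means per 12 h. Errors of changes and slopes are standard errors of the fit. SDs of RAS-OFF intensities are over 10 arrays and so include differences between times. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 31 lists, with the correlation estimated from the data as an alternative.

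The design, the 31 gene lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. The rule named 8 genes whatever their values, of which 2 were not measured under a single gene name here. It also named the 8 largest rises and 8 largest falls without overlap between RAS-OFF and RAS-ON values, up to 3 called members of each list with the largest change, the 5 steepest rises and 5 steepest falls over time, and the 2 largest rises and 2 largest falls at each time. Provisional symbols were passed over outside the lists. In all, 119 genes were named.

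The alternative settings fixed then were leaving out the dimmest 40% of genes, averaging the probe sets of a gene, centring arrays on their medians, eBayes with trend and robust settings, array weights, the replicate number as a block, each array left out in turn, each RAS-OFF time left out in turn, all probe sets tested separately, a minimum change of 1 log2 unit (0.25 per 12 h for the slope), 2 groups only, and a regression within the 10 RAS-OFF arrays. After the data were seen, 3 more were added: without 3 RAS-OFF arrays that stood apart (48 h, 84 h and 96 h replicate 1), with RAS-ON arrays 1 to 3 only, and with RAS-ON arrays 4 and 5 only. Where 1 array of a time was left out, the remaining one was assumed to vary like the other groups.

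The code was tested on simulated data made from the RAS-ON means and residual SDs of the 18193 genes. For RAS-OFF against RAS-ON, 92% of 100 genes changed by 0.5 log2 units and 99% of 100 changed by 1 were recovered, with 16 other genes called. For 48 h against RAS-ON the shares were 63% and 92%, with 10 other genes called. For the slope, 39% of 100 genes at 0.1 per 12 h and 92% at 0.25 were recovered, with 9 other genes called. In a simulated shift of 1 list by 0.5 log2 units, camera called that list and 0 of the other 30. These simulations have no correlation between genes.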

Results

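Gene expression was measured on 15 Affymetrix arrays of acute myeloid leukemia cells taken from the spleens of mice. The leukemia carries the Mll-AF9 fusion gene together with an oncogenic NRAS transgene that doxycycline turns off. SCID/Beige mice, which lack most lymphocytes, received the leukemia cells through the tail vein and had over 100000 white blood cells per microlitre at 20 days. The RAS-ON group holds 5 arrays from vehicle-treated mice at 0 h. The RAS-OFF groups hold 2 arrays each at 48, 60, 72, 84 and 96 h after the start of doxycycline, 10 arrays in all. The median intensity lay between 149.99 and 156.53 on every array. Depth has no counterpart on arrays, and the number of arrays limits the precision. The 3-prime minus 5-prime difference of the Gapdh control probe sets, a sign of RNA integrity, was 1.22 on the log2 scale in RAS-OFF 96 h replicate 1 and 0.10 to 0.35 on the others.

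The comparison of RAS-OFF with RAS-ON leukemias asks which genes differ after doxycycline turned NRAS off. The share of leukemic cells in each spleen was not measured. In the same arrays the median log2 change was 1.40 for erythroid, 0.66 for red pulp macrophage and 0.46 for megakaryocyte genes (adjusted p = 0.0293, 0.22 and 0.22 with an estimated correlation). Of 17 measured genes of RAS-ERK feedback and output, 9 fell, 2 rose and 6 did not pass the test. Etv5, an ETS transcription factor induced by ERK, fell by 2.04 ± 0.09 (SE) on the log2 scale. Its log2 intensity was 9.76 ± 0.21 (SD, n = 5) in RAS-ON and 7.72 ± 0.20 (SD, n = 10) in RAS-OFF arrays. Ccnd1, which encodes cyclin D1, fell by 1.37 ± 0.14 (SE), and the receptor gene Epha2 fell by 1.37 ± 0.18 (SE). The median log2 change of this list was -0.41, with all 10 RAS-OFF arrays below the 5 RAS-ON arrays. limma's camera test gave an adjusted p of 0.00387 for the list and an adjusted p of 0.22 with an estimated correlation. Of 14 immediate early genes, the first transcripts to answer growth factor signals, 10 fell and 1 rose, with a median of -0.77. Klf4, also a member of the monocyte and macrophage list, fell by 2.00 ± 0.12 (SE). Fos fell by 1.95 ± 0.09 and Egr1 by 1.71 ± 0.11. Each of these genes was lower in 10 of 10 RAS-OFF arrays than in any RAS-ON array. The camera adjusted p of the immediate early list was 0.000986, and the adjusted p was 0.22 with an estimated correlation.

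Nras itself was lower by a small amount. Its log2 intensity was 10.94 ± 0.18 (SD, n = 5) in RAS-ON and 10.62 ± 0.17 (SD, n = 10) in RAS-OFF arrays, and the fall of 0.31 ± 0.09 (SE) had an adjusted p of 0.00725 in limma. All 3 Nras probe sets were lower, by 0.25, 0.28 and 0.31 on the log2 scale. The labels do not say whether these probe sets, made for the mouse gene, read the transgene. The Nras call was lost against RAS-ON arrays 1 to 3 alone, where the change was -0.20 with an adjusted p of 0.079. Over all alternatives the adjusted p of Nras ran from 0.00249 to 0.185.

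Genes linked to self-renewal moved both ways, as did the 18193 genes as a whole, of which 3656 were higher and 5219 lower. Myb, a transcription factor of blood progenitors, fell by 0.62 ± 0.07 (SE), with an adjusted p of 2.64e-06 and all 10 RAS-OFF arrays below the RAS-ON arrays. Myc fell by 0.41 ± 0.10 (SE; adjusted p = 0.00348), a call lost against RAS-ON arrays 4 and 5 alone (adjusted p = 0.157, the highest over all alternatives, with 1.73e-05 the lowest). Kit, the stem cell factor receptor, rose by 0.43 ± 0.10 (SE; adjusted p = 0.00263). Hoxa9 and Meis1, a pair of homeobox genes that MLL fusions activate, had changes of -0.24 ± 0.10 (SE; adjusted p = 0.0554) and 0.08 ± 0.13 (SE; adjusted p = 0.657). Against RAS-ON arrays 4 and 5 alone the changes were -0.45 (adjusted p = 0.000954) for Hoxa9 and 0.47 (adjusted p = 0.00745) for Meis1. Hoxa9 passed in 8 of 30 alternatives, among them without RAS-ON replicate 1 (adjusted p = 0.045) and RAS-ON replicate 2 (0.0039). Without RAS-OFF 84 h replicate 1 its change was -0.27. Its highest adjusted p, 0.738, came with the replicate block, where the change turned upward. Meis1 passed in 1 of 30, with adjusted p values up to 0.964. Of 20 measured genes of the HOXA cluster and MLL-fusion targets, 5 rose, 7 fell and 8 did not pass. Among them Mef2c fell by 1.60 ± 0.07 (SE), while Mecom rose by 1.26 ± 0.16 and Pbx3 by 0.95 ± 0.09. The list as a whole had a median of 0.03, a mean of -0.02 and an adjusted p of 0.923. Of 20 stem and progenitor genes, 9 rose and 6 fell. The erythroid list rose in the same arrays, with a median of 1.40. Erythroid cells also express some of these stem genes, such as Tal1 and Gfi1b. The arrays do not separate a change within cells from a change in their share. Cd34, a progenitor surface marker, fell by 1.95 ± 0.12 (SE) and the repressor gene Gfi1 by 1.47 ± 0.09, while Tal1, a transcription factor of stem, erythroid and megakaryocyte cells, rose by 1.30 ± 0.11. That list had a median of 0.15, a mean of -0.01 and an adjusted p of 0.515, with an upward direction in the test.

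All 8 measured genes of the azurophil granule and promyelocyte list fell, with a median log2 change of -1.93. Promyelocytes make azurophil granules. The list median was lower in 10 of 10 RAS-OFF arrays than in any RAS-ON array. The erythroid and red pulp macrophage lists, with medians of 1.40 and 0.66, moved the other way in these arrays, and the arrays do not separate a change within cells from a change in their share. Ctsg, which encodes cathepsin G, had a log2 intensity of 12.98 ± 0.12 (SD, n = 5) in RAS-ON and 10.32 ± 0.26 (SD, n = 10) in RAS-OFF arrays, a fall of 2.66 ± 0.10 (SE). Cst7 fell by 2.30 ± 0.09 (SE) and Elane, the neutrophil elastase gene, by 2.07 ± 0.12. The adjusted p of the list was 1.29e-06, and the adjusted p was 0.22 with an estimated correlation. Of 17 genes of later neutrophil granules and maturation, 10 rose and 1 fell, with a median of 0.30. Mmp8, neutrophil collagenase, rose by 2.17 ± 0.08 (SE), the chemokine receptor gene Cxcr2 by 1.81 ± 0.10 and Mmp9 by 1.20 ± 0.11. This list had an adjusted p of 3.89e-05 and an adjusted p of 0.22 with an estimated correlation. Of 23 monocyte and macrophage genes, 12 fell and 4 rose, with a median of -0.25 and an adjusted p of 0.0539. The monocyte list passed in 10 of 25 alternatives, with adjusted p values from 0.00934 (RAS-ON arrays 1 to 3 alone) to 0.34 over all of them. The single arrays without which it passed were RAS-ON replicates 1, 4 and 5 (0.0358, 0.0246 and 0.0328) and RAS-OFF 60 h replicate 1, 72 h replicate 1 and 96 h replicate 2 (0.0419, 0.0439 and 0.0417). F13a1 fell by 2.21 ± 0.08 (SE) and Cx3cr1 by 1.33 ± 0.19. Klf4, also in the immediate early list, fell as given above. Among 11 mast cell and eosinophil genes 4 rose and 2 fell, with a median of -0.04, a mean of 0.05 and an adjusted p of 0.784. The basophil protease gene Mcpt8 fell by 2.21 ± 0.25 (SE), and the eosinophil granule genes Prg2 and Epx rose by 1.72 ± 0.32 and 1.30 ± 0.31. The Epx call was lost against RAS-ON arrays 4 and 5 alone (change 0.36, adjusted p = 0.276, the highest over all alternatives, with 1.45e-05 the lowest).

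Genes of erythroid cells were higher after the switch. Of 14 measured erythroid genes 12 rose and none fell, with a median log2 change of 1.40. Epb42, a red cell membrane protein gene, rose by 2.43 ± 0.11 (SE), Car1, a carbonic anhydrase gene, by 2.39 ± 0.10 and Ermap by 1.76 ± 0.09. The log2 intensity of Car1 was 10.31 ± 0.23 (SD, n = 5) in RAS-ON and 12.70 ± 0.19 (SD, n = 10) in RAS-OFF arrays. The list had an adjusted p of 2.21e-11, and it alone of the 31 lists kept its call with an estimated correlation (adjusted p = 0.0293). The remaining 2 members, the alpha-globin genes Hba-a1 and Hba-a2, had log2 intensities near 6.05 and 6.51 in RAS-ON arrays and changes of 0.04 and 0.01. Each was read by 1 probe set with a single gene name, whose signal lay below the median of every array.

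Of 14 genes of red pulp macrophages, the iron-recycling cells of the spleen, 10 rose and 1 fell, with a median of 0.66 (adjusted p = 2.78e-05; adjusted p = 0.22 with an estimated correlation). Timd4 rose by 1.21 ± 0.07 (SE), the iron exporter gene Slc40a1 by 1.03 ± 0.06 and Vcam1 by 1.02 ± 0.10. Of 11 megakaryocyte and platelet genes 9 rose and none fell, with a median of 0.46 (adjusted p = 2.78e-05; adjusted p = 0.22 with an estimated correlation), among them Itgb3 by 0.68 ± 0.08 (SE), Vwf by 0.65 ± 0.05 and Gp1bb by 0.59 ± 0.10. Of 21 stroma and endothelium genes 12 rose and 4 fell, with a median of 0.28 (adjusted p = 0.0035; adjusted p = 0.22 with an estimated correlation). Cxcl12, a chemokine of marrow and spleen stroma, rose by 1.58 ± 0.07 (SE) on its brightest probe set, while 1 of its 3 probe sets passed the test in the other direction. Stab2 rose by 1.18 ± 0.10 (SE) and Pdgfrb by 0.94 ± 0.07. The stroma list had a median of -0.10 at 96 h and of 0.26 to 0.39 at the other times. At 96 h it stood at 0.18 in replicate 1, the array with the high Gapdh difference, and at -0.14 in replicate 2. Of 10 natural killer cell genes 6 rose, with a median of 0.29 (adjusted p = 0.0152; adjusted p = 0.221 with an estimated correlation), among them Gzma by 0.94 ± 0.12 (SE), Ncr1 by 0.69 ± 0.14 and Tbx21 by 0.61 ± 0.07. This call was lost with the dimmest genes left out (adjusted p = 0.15) and against RAS-ON arrays 4 and 5 alone (adjusted p = 0.0775), where the range over all alternatives was 0.00384 to 0.221.

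The B-cell, T-cell, dendritic cell and MHC class II lists did not pass. Of 11 B-cell genes 3 rose and 5 fell (median -0.13, adjusted p = 0.546), with Cd79b falling by 1.41 ± 0.12 (SE), Cd22 falling by 0.44 ± 0.08 and Fcrla rising by 0.61 ± 0.08. Of 9 T-cell genes 2 rose and 1 fell (median 0.09, adjusted p = 0.208), with Cd3d rising by 1.26 ± 0.10 (SE), Cd8a rising by 0.22 ± 0.06 and Cd5 falling by 0.55 ± 0.08. Of 11 dendritic cell genes 6 rose and 1 fell (median 0.22, adjusted p = 0.081, with a pass in 3 of 25 alternatives), and Flt3 rose by 0.73 ± 0.12 (SE), Zbtb46 by 0.68 ± 0.22 and Ly75 by 0.64 ± 0.10. The dendritic cell list passed without RAS-ON replicate 3 (adjusted p = 0.0336) and against RAS-ON arrays 4 and 5 alone (adjusted p = 0.0274), the lowest over all alternatives, with 0.22 the highest. Of 8 genes of MHC class II presentation 3 rose and 2 fell (median 0.12, adjusted p = 0.546). H2-DMa fell by 0.39 ± 0.09 (SE) and Ctss by 0.26 ± 0.05, while H2-Oa rose by 0.36 ± 0.08. The H2-Oa call was lost against RAS-ON arrays 4 and 5 alone (adjusted p = 0.192), and the Cd8a and Zbtb46 calls against RAS-ON arrays 1 to 3 alone (adjusted p = 0.0775 and 0.0723). Over all alternatives the adjusted p ran from 5.38e-05 to 0.192 for H2-Oa, 1.62e-05 to 0.332 for Cd8a and 0.00184 to 0.0973 for Zbtb46. The Zbtb46 call was also lost in the mean of its probe sets (adjusted p = 0.0973), without RAS-ON replicate 1 (adjusted p = 0.0555) and without the 3 RAS-OFF arrays that stood apart (adjusted p = 0.0659), and without RAS-ON replicate 4 its change was 0.40.

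Of 26 genes of DNA replication and S phase 18 rose and 2 fell, with a median of 0.29 (adjusted p = 3.89e-05; adjusted p = 0.22 with an estimated correlation). Ccne2, which encodes cyclin E2, rose by 1.03 ± 0.08 (SE), Cdc6 by 0.77 ± 0.07 and Ccne1 by 0.67 ± 0.06. Of 23 genes of mitosis 13 rose and 4 fell, with a median of 0.19 (camera adjusted p = 0.00204, and 0.275 with an estimated correlation). Nusap1 rose by 0.66 ± 0.06 (SE), Mki67 by 0.58 ± 0.05 and Cenpf by 0.58 ± 0.07. The medians of the replication and mitosis lists each lay above all RAS-ON arrays in 7 of 10 RAS-OFF arrays and below them in 1. The mitosis median against RAS-ON was 0.053 at 48 h, -0.013 at 60 h, 0.225 at 72 h, 0.352 at 84 h and 0.299 at 96 h. Of 15 glycolysis genes 11 fell and 3 rose, with a median of -0.82, beside 1.40 for erythroid genes, and all 10 RAS-OFF arrays below the RAS-ON arrays (adjusted p = 0.000983; adjusted p = 0.22 with an estimated correlation). The pyruvate kinase gene Pkm fell by 1.51 ± 0.14 (SE), Pgam1 by 1.46 ± 0.07 and Pfkp by 1.34 ± 0.08. Of 17 cholesterol synthesis genes 12 fell and 2 rose, with a median of -0.49 (adjusted p = 0.00204; adjusted p = 0.22 with an estimated correlation), and Fdps fell by 1.11 ± 0.08 (SE), Cyp51 by 1.02 ± 0.10 and Insig1 by 0.88 ± 0.09. Of 26 genes of MYC output and ribosome biogenesis 14 fell and 2 rose, with a median of -0.27 and an adjusted p of 0.0525. The MYC list passed in 12 of 25 alternatives, with adjusted p values from 0.00934 (RAS-ON arrays 1 to 3 alone) to 0.605 over all of them. The single arrays without which it passed were RAS-ON replicates 4 and 5 (0.018 and 0.042) and RAS-OFF 48 h replicate 1, 60 h replicate 2, 72 h replicate 1, 84 h replicate 1 and 96 h replicate 2 (0.0374, 0.0479, 0.0414, 0.0322 and 0.0101). Bop1 and Nop16, which encode ribosome assembly factors, fell by 0.68 ± 0.09 (SE) and 0.67 ± 0.10, while Mthfd2, a mitochondrial folate enzyme gene, rose by 0.69 ± 0.07. Of 24 oxidative phosphorylation genes 7 fell and 2 rose (median -0.03, adjusted p = 0.489), with Sdhb lower by 0.38, Ndufb5 by 0.35 and Ndufb8 by 0.28.

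Of 18 genes of the ATF4 stress response 11 rose and 3 fell, with a median of 0.50 (adjusted p = 0.000983; adjusted p = 0.22 with an estimated correlation). Asns, asparagine synthetase, rose by 1.59 ± 0.06 (SE) and Trib3 by 1.17 ± 0.11, while Cebpb, a myeloid transcription factor, fell by 1.51 ± 0.08. Of 22 interferon response genes 13 rose and 1 fell, with a median of 0.35 (adjusted p = 2.78e-05; adjusted p = 0.221 with an estimated correlation), and Rsad2 rose by 2.13 ± 0.07 (SE), Oasl2 by 1.72 ± 0.26 and Usp18 by 1.66 ± 0.22. Of 19 FOXO targets 9 rose and 3 fell, with a median of 0.17 (adjusted p = 0.0377; adjusted p = 0.439 with an estimated correlation). Gadd45a rose by 1.69 ± 0.06 (SE), while Ddit4 fell by 1.32 ± 0.29 and Pik3ip1 by 1.27 ± 0.24. The FOXO call was lost without RAS-ON replicate 2, RAS-ON replicate 3 or RAS-OFF 96 h replicate 1, at adjusted p values of 0.0784, 0.0692 and 0.0594. It was also lost in the mean of probe sets (0.395), without the dimmest genes (0.0742), without the 3 RAS-OFF arrays that stood apart (0.0558) and against RAS-ON arrays 4 and 5 alone (0.59), with 0.0053 the lowest adjusted p over all alternatives.

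Of 16 p53 targets 2 rose and 4 fell (median 0.00, mean -0.06, upward direction in the test, adjusted p = 0.951). Cdkn1a fell by 0.87 ± 0.13 (SE) and Pmaip1, also called Noxa, by 0.81 ± 0.11. Trp53inp1 was higher by 0.60 ± 0.21 (SE; adjusted p = 0.0273), and its call was lost without any 1 of RAS-ON replicates 1, 2 and 3, at adjusted p values of 0.0868, 0.0868 and 0.082. Against RAS-ON arrays 4 and 5 alone its direction turned, with a change of -0.10 and an adjusted p of 0.625, and against arrays 1 to 3 alone the change was 1.06 with an adjusted p of 2.78e-08, the ends of the range over all alternatives. The Trp53inp1 call was also lost in the mean of its probe sets (0.108), with trend and robust settings (0.0579), without the 48 h arrays (0.0534) and without the 3 RAS-OFF arrays that stood apart (0.0688). Of 10 pro-death BCL2 family genes 5 fell and 1 rose (median -0.19, adjusted p = 0.162), with Bak1 falling by 1.23 ± 0.12 (SE) and Bid by 1.08 ± 0.07. Of 4 anti-death family genes Bcl2 fell by 1.57 ± 0.07 (SE) and Bcl2l1 rose by 0.51 ± 0.07 (list median -0.05, adjusted p = 0.783). The Bcl2l1 call was lost in the mean of its 4 probe sets (change 0.12, adjusted p = 0.136, the highest over all alternatives, with 1.02e-05 the lowest). Of 19 NF-kB and inflammation genes 10 fell and 4 rose (median -0.28, adjusted p = 0.178). The chemokine genes Ccl3 and Cxcl2 fell by 1.53 ± 0.09 (SE) and 0.85 ± 0.09, and Il1b rose by 1.35 ± 0.11. Of 9 heat shock genes, which can mark handling of the tissue, 3 rose (median 0.12, adjusted p = 0.0574, with a pass in 6 of 25 alternatives), among them Dnajb1 by 0.89 ± 0.06 (SE), Hsph1 by 0.59 ± 0.19 and Hspe1 by 0.28 ± 0.07. The heat shock list passed without RAS-ON replicate 2 (adjusted p = 0.0223), RAS-ON replicate 3 (0.019) or RAS-OFF 60 h replicate 2 (0.0338), and its adjusted p ran from 0.0012 to 0.446 over all alternatives. The Hsph1 call was lost without RAS-ON replicate 4 or 5, at adjusted p values of 0.058 and 0.0547, with a change of 0.39 without replicate 5. It was also lost without the 60 h arrays (0.0537), without the 3 RAS-OFF arrays that stood apart (0.0586) and against RAS-ON arrays 1 to 3 alone (0.225), while the lowest adjusted p of Hsph1 over all alternatives was 2.55e-06.

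Cdh17, an intestinal and hematopoietic cadherin gene, had a log2 intensity of 10.42 ± 0.33 (SD, n = 5) in RAS-ON and 6.46 ± 0.14 (SD, n = 10) in RAS-OFF arrays, a fall of 15.5-fold (adjusted p = 8.67e-12 in limma). Gem, a small GTPase gene, fell 14.2-fold and Cdh1, which encodes E-cadherin, fell 8.74-fold. Sgip1, Dmkn, Tctex1d1, Bex6 and Rnase2a fell 6.42-fold to 7.41-fold. Il1bos, annotated opposite Il1b, rose from a log2 intensity of 4.71 ± 0.24 (SD, n = 5) to 8.58 ± 0.26 (SD, n = 10). The lower of the group means of Il1bos, Cdh1 and Tctex1d1 lay below the lower quartile of every array, so the sizes of these 3 changes are uncertain. The embryonic globin gene Hbb-y rose 14.2-fold on a probe set whose class can bind related transcripts, so globin family values are uncertain. Ninl, Prokr1, Slc6a20a and Pla2g4c rose 4.78-fold to 6.20-fold. In every one of these genes the 10 RAS-OFF values lay on one side of the 5 RAS-ON values.

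Over 18193 genes, 8875 differed at an adjusted p below 0.05 in limma, 3656 higher and 5219 lower in RAS-OFF arrays. Of these, 691 changed by at least 1 log2 unit, 430 upward and 261 downward. In 1701 of the called genes every RAS-OFF value lay above every RAS-ON value and in 2179 every one lay below, where chance gives 0.0333% on each side. Doxycycline and elapsed time were not varied apart from NRAS, so the 3 cannot be told apart in this comparison. Counts adjusted over the list alone equalled those above in 21 of the 31 lists. In the other 10 they were 8 lower for HOXA and MLL-fusion targets, 10 higher and 7 lower for stem genes, 12 higher and 2 lower for neutrophil genes, 13 lower for monocyte genes and 15 lower for MYC genes. They were 1 higher for oxidative phosphorylation, 12 higher for ATF4 genes, 14 higher for interferon genes, 11 lower for NF-kB genes and 10 higher for megakaryocyte genes.

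**Figure D1:**
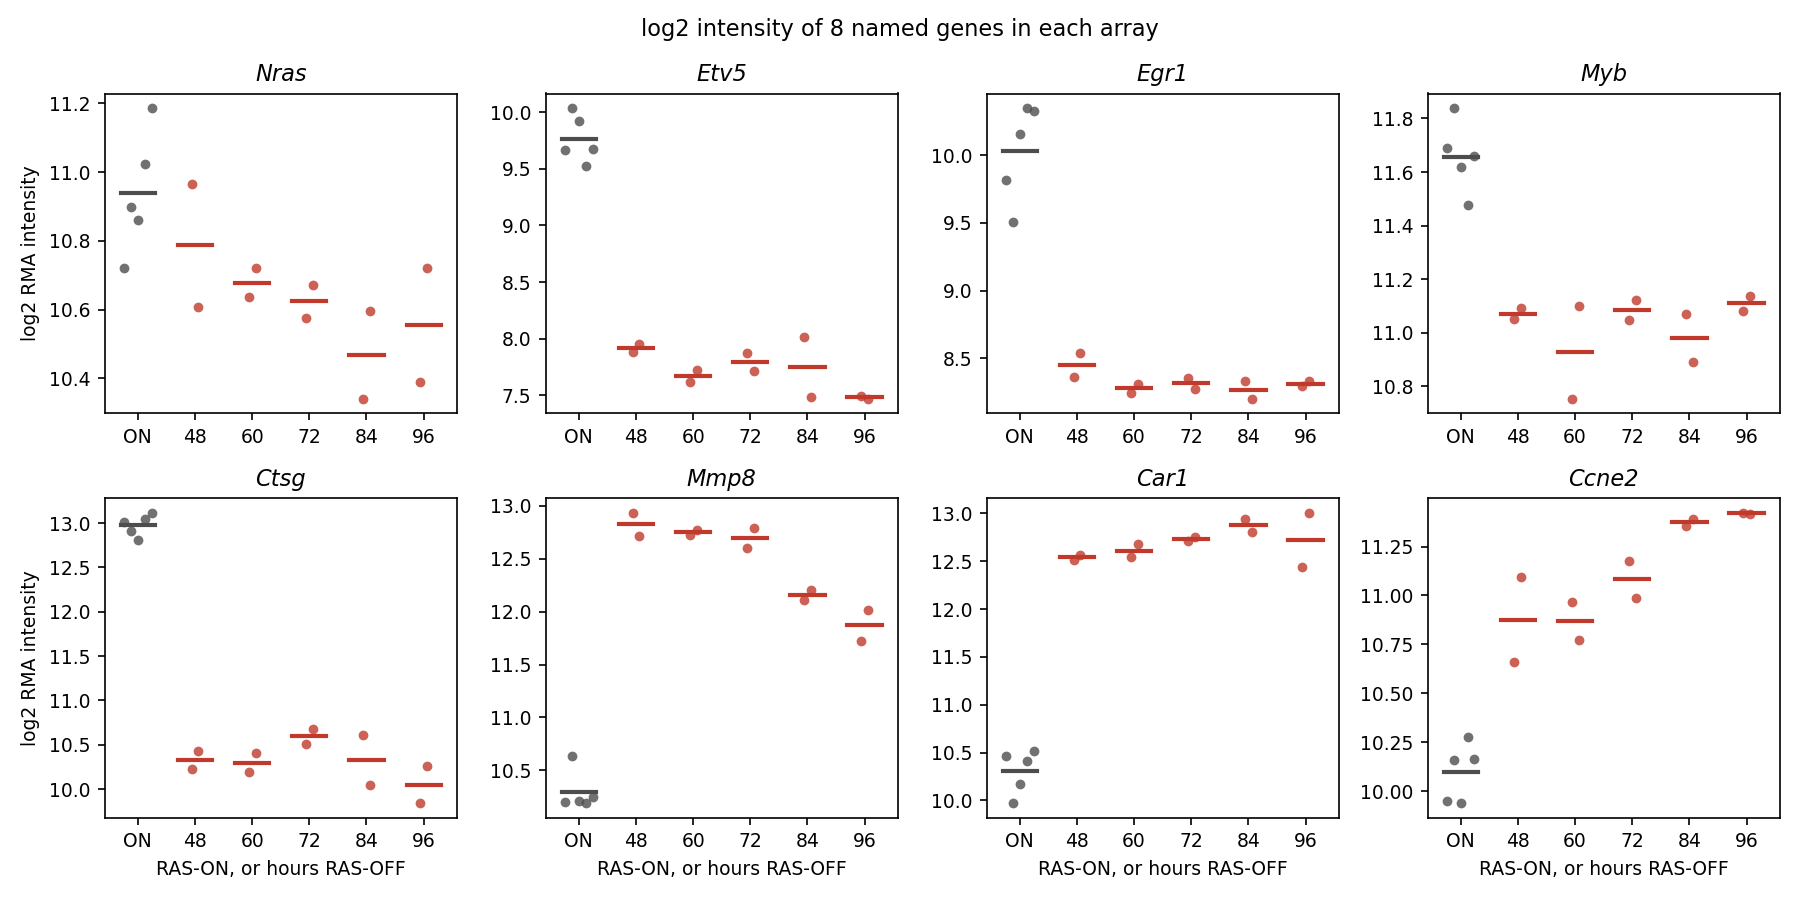
Log2 RMA intensity (vertical axis) of 8 named genes in each array, for RAS-ON and for each RAS-OFF time in hours (horizontal axis); points are arrays and bars are group means. Etv5 lies at 9.76 in the mean of RAS-ON and at 7.72 in that of RAS-OFF arrays, and Car1 at 10.31 and 12.70.

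The comparisons at single times ask how early the changes were present. The same genes led at each time. Cdh17 had a log2 change of -4.04 ± 0.18 (SE) at 48 h and -3.98 at 96 h, and Gem one of -3.64 ± 0.22 and -4.01. Il1bos was higher by 3.78 ± 0.18 (SE) at 48 h and 3.87 at 96 h, and Hbb-y by 3.60 ± 0.23 and 3.90. By the measured values these 4 genes were the 2 largest falls and 2 largest rises at all 5 times, where the dim RAS-ON signal of Il1bos leaves its size and rank uncertain. The numbers of genes that differed from RAS-ON were 4987 at 48 h (2494 higher, 2493 lower) and 4686 at 60 h (2094 higher, 2592 lower). They were 5779 at 72 h (2442 higher, 3337 lower), 6700 at 84 h (2738 higher, 3962 lower) and 6847 at 96 h (3045 higher, 3802 lower). With a change of at least 1 log2 unit as well, 415 were higher and 147 lower at 48 h, 327 and 178 at 60 h, 480 and 283 at 72 h, 536 and 470 at 84 h, and 500 and 501 at 96 h. With 1 of the 2 arrays of a time left out, the count fell to 2911 at 48 h (without replicate 2; 3126 without replicate 1), 2417 at 60 h (without replicate 1; 3024 without replicate 2), 3436 at 72 h (without replicate 1) and 4283 at 84 h (without replicate 2). All 5 comparisons share the RAS-ON arrays, so their counts are not independent.

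**Figure D2:**
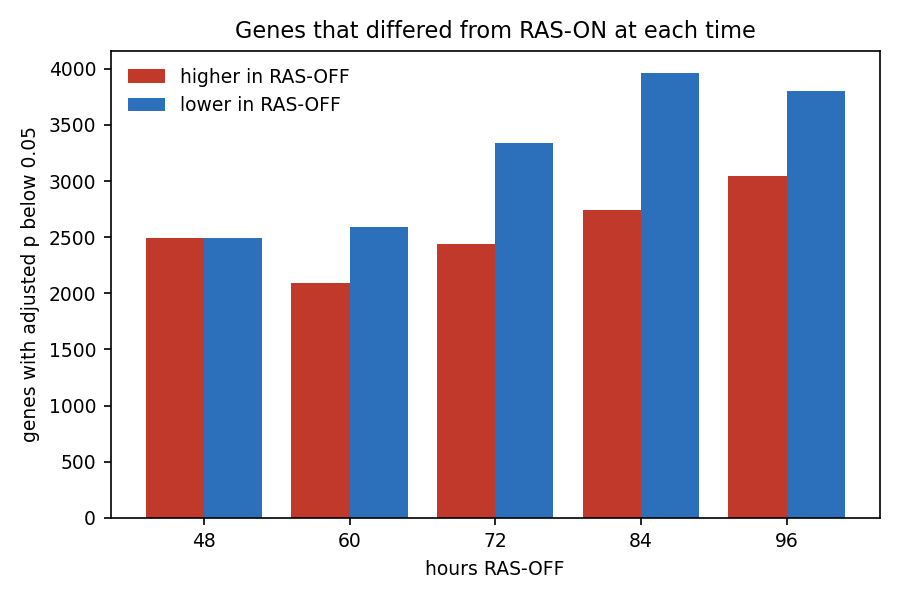
Number of genes (vertical axis) with an adjusted p below 0.05 against RAS-ON at each RAS-OFF time in hours (horizontal axis), higher and lower in separate bars that start at 0. At 96 h 3045 genes were higher and 3802 lower.

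The slope over RAS-OFF time asks which genes kept moving between 48 and 96 h, and it does not use the RAS-ON level. In the DNA replication list 21 of 26 genes had a rising slope and none a falling one (25 adjusted over the list alone), with a median of 0.11 log2 units per 12 h. Its median against RAS-ON was 0.11 at 48 h, -0.05 at 60 h, 0.28 at 72 h, 0.43 at 84 h and 0.45 at 96 h. The list had an adjusted p of 1.8e-18 in camera and an adjusted p of 0.0363 with an estimated correlation. In the mitosis list 14 of 23 genes rose (19 adjusted over the list alone), with a median of 0.09 (adjusted p = 6.66e-11; adjusted p = 0.0652 with an estimated correlation). Cdc6 rose by 0.17 ± 0.03 (SE) per 12 h and Cenpf by 0.17 ± 0.03. The erythroid list rose by a median of 0.06, with 5 of 14 genes past the test (5 adjusted over the list alone; adjusted p = 0.000236; adjusted p = 0.0925 with an estimated correlation), and stood at 1.21 at 48 h and 1.49 at 96 h.

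In the neutrophil list 13 of 17 genes fell (14 adjusted over the list alone), with a median of -0.17 per 12 h (adjusted p = 2.3e-11; adjusted p = 0.0681 with an estimated correlation). Its median against RAS-ON was 0.43 at 48 h and 0.07 at 96 h. Mmp8 fell by 0.25 ± 0.03 (SE) and Cxcr2 by 0.31 ± 0.04 per 12 h. In the monocyte list 11 of 23 genes fell (16 adjusted over the list alone; median -0.12, adjusted p = 2.25e-09; adjusted p = 0.0363 with an estimated correlation). In the glycolysis list 10 of 15 fell (11 adjusted over the list alone; median -0.13, adjusted p = 6.43e-09; adjusted p = 0.0363 with an estimated correlation), Pkm by 0.29 ± 0.06 (SE) per 12 h. In the dendritic cell list 5 of 11 fell (6 adjusted over the list alone; median -0.10, adjusted p = 0.0018; adjusted p = 0.0477 with an estimated correlation). The azurophil list fell in 4 of 8 genes (5 adjusted over the list alone; median -0.13, adjusted p = 0.000275; adjusted p = 0.284 with an estimated correlation), Elane by 0.26 ± 0.05 (SE) per 12 h.

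A further 8 lists had falling slopes whose calls were lost with an estimated correlation. MHC class II genes fell in 5 of 8 (8 adjusted over the list alone; median -0.10, adjusted p = 3.47e-05; adjusted p = 0.0925 with an estimated correlation). Natural killer cell genes fell in 5 of 10 (7 adjusted over the list alone; median -0.11, adjusted p = 0.000275; adjusted p = 0.0925 with an estimated correlation). Stroma genes fell in 5 of 21 (9 adjusted over the list alone; median -0.06, adjusted p = 0.000745; adjusted p = 0.149 with an estimated correlation), and the median was -0.10 without 96 h replicate 1 and -0.03 without 96 h replicate 2. Interferon genes fell in 3 of 22 (8 adjusted over the list alone; median -0.07, adjusted p = 0.000822; adjusted p = 0.354 with an estimated correlation), a call lost without RAS-OFF 48 h replicate 2 (median -0.03, adjusted p = 0.0807), with 4.27e-07 the lowest over all alternatives. Immediate early genes fell in 4 of 14 (6 adjusted over the list alone; median -0.08, adjusted p = 0.0054; adjusted p = 0.138 with an estimated correlation). FOXO targets fell in 5 of 19 and rose in 1 (9 and 1 adjusted over the list alone; median -0.08, adjusted p = 0.00679; adjusted p = 0.351 with an estimated correlation), a call also lost without the dimmest genes (adjusted p = 0.116). Red pulp macrophage genes fell in 2 of 14 (2 adjusted over the list alone; median -0.05, adjusted p = 0.0312; adjusted p = 0.432 with an estimated correlation), a call lost without 48 h replicate 1 (adjusted p = 0.0839), 84 h replicate 1 (adjusted p = 0.0587) or 96 h replicate 1 (adjusted p = 0.126). The red pulp slope was also lost without all 3 of these arrays (adjusted p = 0.405) and without the dimmest genes (adjusted p = 0.246), with 0.0109 the lowest over all alternatives. Cholesterol synthesis genes fell in 3 of 17 (6 adjusted over the list alone; median -0.05, adjusted p = 0.0312; adjusted p = 0.354 with an estimated correlation), a call lost without 48 h replicate 2 (adjusted p = 0.108) or 84 h replicate 2 (adjusted p = 0.0575). The cholesterol slope was also lost in the mean of probe sets (adjusted p = 0.066) and without the dimmest genes (adjusted p = 0.238), with 0.0094 the lowest over all alternatives. The other 15 lists had median slopes from -0.08 to 0.02 and did not pass with the settings above. Of these, the p53 slope passed in 12 of 25 alternatives (lowest adjusted p 0.0109, highest 0.335), the NF-kB slope in 5 (0.00765 and 0.598), the heat shock slope in 3 (0.0295 and 0.642) and the oxidative phosphorylation slope in 2 (0.0156 and 0.825). The MYC (lowest 0.00221, highest 0.783), ATF4 (0.0222 and 0.708), stem gene (0.0352 and 0.708) and RAS-ERK slopes (0.0325 and 0.445) passed in 1 each. Single arrays whose removal gave a pass for p53 targets were RAS-ON replicates 1, 2 and 4 (0.0457, 0.0484 and 0.0443), 60 h replicate 1 (0.0465), both 72 h replicates (0.0473 each), 84 h replicate 1 (0.0442) and 96 h replicate 1 (0.0225). Without 96 h replicate 1 the NF-kB and oxidative phosphorylation slopes passed (0.00765 and 0.0156), and the latter had a median of 0.03. Without 96 h replicate 2 the MYC slope passed with a median of -0.05, against -0.02 with all arrays. Heat shock genes passed without 48 h replicate 1 (0.0343) or 60 h replicate 2 (0.0295). Median and mean differed in sign for B-cell genes (0.01 and -0.01, upward in the test), T-cell genes (0.02 and -0.01, upward) and mast cell and eosinophil genes (-0.02 and 0.02, downward). Among these 15 lists the counts adjusted over the list alone differed for heat shock genes, with 1 rising and 4 falling in place of 0 and 3, and for B-cell genes, with 2 rising and 2 falling in place of 2 and 0.

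The steepest single rises per 12 h were those of Tac2 at 0.37 ± 0.04 (SE), Slc6a20a at 0.36 ± 0.08, Ddx4 at 0.35 ± 0.03, St6galnac3 at 0.34 ± 0.05 and Aldh1a7 at 0.33 ± 0.05. The low signal of Ddx4 leaves the size and rank of its slope uncertain. The steepest falls were those of Pglyrp1, a neutrophil granule protein gene, at -0.46 ± 0.07 (SE), Slfn1 at -0.43 ± 0.06, Clec5a at -0.42 ± 0.07, the gamma-delta T-cell receptor segment Trgv4 at -0.41 ± 0.10 and Ankrd22 at -0.40 ± 0.05. The slope passed in 2501 genes, 909 rising and 1592 falling. With a slope of at least 0.25 per 12 h as well, 11 were rising and 102 falling. The count was 1109 without RAS-OFF 48 h replicate 1, and 448 (86 rising, 362 falling) without 3 RAS-OFF arrays that stood apart from the rest, 1 each at 48, 84 and 96 h. Without 48 h replicate 1, Slc6a20a and Trgv4 had slopes of 0.32 and -0.40 (adjusted p = 0.0623 and 0.0748), and without 96 h replicate 1 Trgv4 had a slope of -0.35 (adjusted p = 0.0878). Without the 3 arrays the slopes were 0.32 for Slc6a20a, -0.41 for Trgv4 and 0.29 for Aldh1a7, with adjusted p values of 0.189, 0.116 and 0.0759, the highest over all alternatives, where the lowest were 4.04e-05, 0.00284 and 0.000176.

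**Figure D3:**
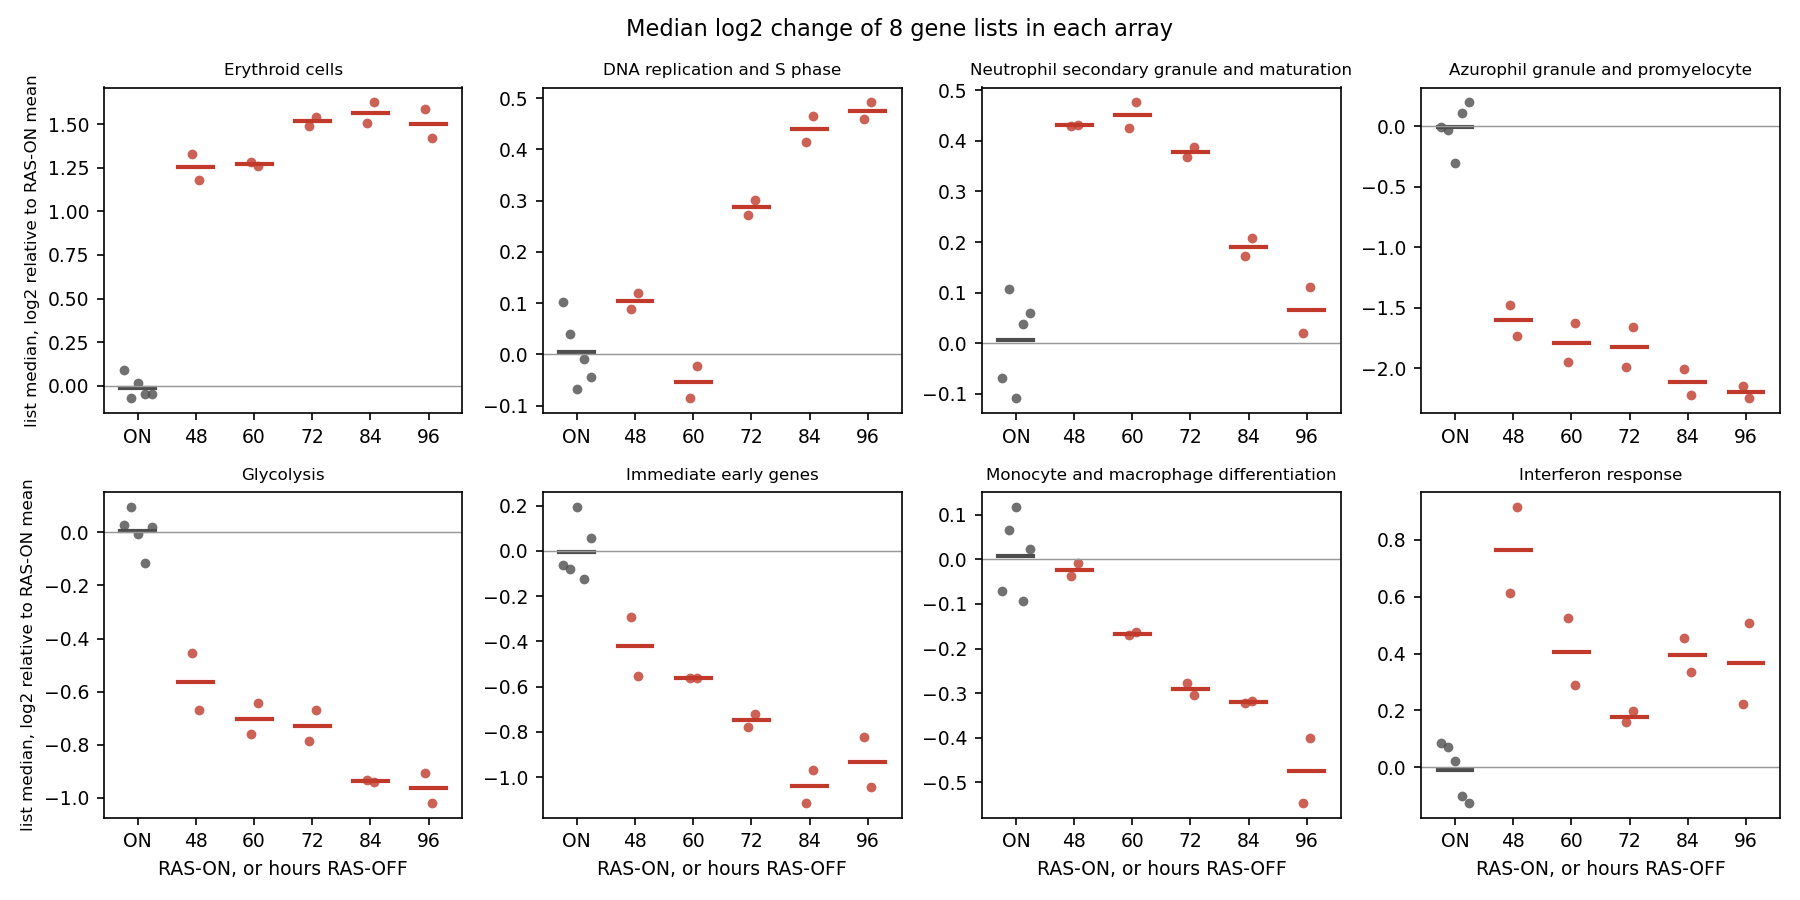
Median log2 change of 8 gene lists relative to the mean of the RAS-ON arrays (vertical axis, scaled separately in each panel) in each array, for RAS-ON and for each RAS-OFF time in hours (horizontal axis); points are arrays and bars are means of the points. The DNA replication list lies at -0.09 and -0.02 in the arrays of 60 h and at 0.46 and 0.49 in those of 96 h.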

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

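The tests in this part that weigh an explanation were chosen after the results they bear on had been seen, and so were the marker lists for pancreas. The rule that weighs a rising erythroid share in the second pattern was changed 2 times after its values were seen.

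A first pattern is the rise of erythroid genes in RAS-OFF spleens. If a smaller share of leukemic cells had raised all resident cell types alike, the erythroid list would have moved with the other resident lists. Its mean log2 change exceeded that of red pulp macrophages, the highest of 7 such lists, by 0.786 ± 0.227 (SE over genes). That error is between genes, not between spleens. The T-cell, B-cell and natural killer cell lists among them are weak comparators, since these mice lack most lymphocytes. The erythroid list was higher in 10 of 10 RAS-OFF arrays, although background signal reduces the changes of dim markers unequally. Leukemic cells may also express genes of the other lists, which would lower those lists as the leukemic share fell. The gap therefore does not exclude a smaller leukemic share as the only source. Carry-over of blood cells without precursor transcripts would have left Gata1, Klf1 and Epor near 0, and their mean change was 1.502 ± 0.141 (SE over 3 genes). These genes belong to the erythroid list, whose rise was already known, so their change is not independent of it. A change in erythroid precursors stays open as a hypothesis, beside any fall in the leukemic share, and no test here separates its possible routes. Doxycycline itself and time were not varied apart from NRAS and remain open as well.

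A second pattern is the rise of DNA replication genes over RAS-OFF time. Whether it came from a rising erythroid share stays open, since both lists rose with time, and after removal of the time means, with 2 arrays per time, their medians had an r of -0.133 (exact permutation over all 32 swaps within times, one-sided p = 0.594 for a positive and 0.438 for a negative relation). At 60 h the replication list stood at -0.054 (SD 0.040 within groups) against 0.403 scaled from 96 h by the erythroid list, a scaling that assumes proportional changes and so excludes nothing. The 3 arrays that stood apart were not the source, since the median slope was 0.111 without them (adjusted p = 8.28e-20 in camera). A rising erythroid share and a change of cycling in leukemic cells may each account for the rise, and they cannot be told apart here without a measured profile of either cell type. Other shifts in cell share were not tested. The neutrophil and monocyte lists fell over the same times, with median slopes of -0.166 and -0.125 per 12 h.

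A further pattern is exocrine pancreas transcripts in RAS-OFF 84 h replicate 1. All 20 measured exocrine genes lay more than 1 log2 unit above the highest of the other 14 arrays, with a median gap of 5.07, and Ctrb1, Reg1 and Prss2 stood at 13.50, 13.29 and 13.33. In the other arrays the highest values of these genes ran from 4.45 for Prss3 to 9.91 for Cela1. A response to 84 h without NRAS would have appeared in replicate 2 as well, and there the list median was -0.076, inside the range of -0.191 to 0.064 over the other 13 arrays. Pancreatic tissue taken with that spleen is a candidate source, with 0 of 6 endocrine genes raised by the same margin, and no biological explanation beyond the time point was tested.

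Single RAS-ON arrays stood far from the rest in 3 of 150 genes and lists tested, where chance flags about 1 in 20. Pla2g4c was 8.04 in replicate 5 against 7.60 to 7.72 in the others. Mmp8 was 10.63 in replicate 2 against 10.19 to 10.25. Slc40a1 was 10.85 in replicate 1 against 11.11 to 11.18.

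Effects differed between RAS-OFF times, by the test of the slope per 12 h, in 41 of the 119 named genes, which include 10 named for the steepest slopes, and in 16 lists, of which 4 passed with an estimated correlation. Rising medians were 0.11 for DNA replication, 0.09 for mitosis and 0.06 for erythroid genes. Falling medians were -0.17 for neutrophil, -0.13 for azurophil, -0.13 for glycolysis, -0.12 for monocyte, -0.11 for natural killer, -0.10 for dendritic and -0.10 for MHC class II genes. They were -0.08 for immediate early genes, -0.08 for FOXO targets, -0.07 for interferon, -0.06 for stroma, -0.05 for red pulp macrophage and -0.05 for cholesterol genes. Outside the main measurement, the Gapdh control difference of 1.22 in RAS-OFF 96 h replicate 1 stood above 0.10 to 0.35 in the others. Among 9160 probe sets with no gene name, 2719 differed between RAS-OFF and RAS-ON arrays.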

How the results depend on the processing

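The settings that leave out 3 RAS-OFF arrays or part of the RAS-ON arrays were chosen after the data were seen. The count for RAS-OFF against RAS-ON was 8007 to 8825 with any 1 array or time left out, 6950 without the dimmest genes, 7803 without the 3 arrays that stood apart, and 8529 and 7559 with RAS-ON arrays 1 to 3 or 4 and 5 only. With any 1 array left out, counts at 48, 60, 72 and 84 h and for the slope were 2911 to 5441, 2417 to 5031, 3436 to 6019, 4283 to 6979 and 1109 to 2757, with the highest values without RAS-ON replicate 3, and the cause was not tested. At 96 h the range was 4653 to 7014. Without the 3 arrays the counts were 2834 at 48 h, 4217 at 96 h and 448 for the slope. Tested as separate probe sets, 18711 differed between RAS-OFF and RAS-ON, 8383, 7962, 10912, 13186 and 14517 at 48 to 96 h, and 4636 by slope, since more features were tested. With a minimum change as well, 691 differed between RAS-OFF and RAS-ON, 562, 505, 763, 1006 and 1001 at 48 to 96 h, and 113 by slope. With an estimated correlation, 1 list passed for RAS-OFF against RAS-ON and 4 for the slope, in place of 16 each. Other settings gave 14 to 19 and 13 to 19 lists.

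Replicate numbers did not pair the samples: over 15 pairs of groups the deviations correlated from -0.444 to 0.334, with a median of -0.169 and 2 above 0.1. With the replicate block 7970 genes differed between RAS-OFF and RAS-ON, 5216, 5199, 6239, 7017 and 7051 at 48 to 96 h, and 3250 by slope, with 19 and 18 lists. RAS-ON replicates 3, 4 and 5 have no RAS-OFF counterpart, so the block fitted each of them exactly. It thus compared RAS-OFF with RAS-ON replicates 1 and 2 alone. The replicate block ended the calls of Nras (-0.186, adjusted p = 0.185), Cd8a (adjusted p = 0.332) and Hsph1 (adjusted p = 0.0698), and Hoxa9 stood at 0.045 (adjusted p = 0.738).

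Among named genes called with all arrays or in an alternative, 1 result reversed. Trp53inp1 was -0.098 against RAS-ON arrays 4 and 5 only (adjusted p = 0.625), and the cause was not tested. Sign turns of genes called in neither were not counted, and Hoxa9 turned upward in this way with the replicate block. Named genes kept their call, or lack of one, in 2088 results with 1 array left out and 1884 in other settings. They lost the call in 9 and 22 and gained it in 3 and 6. Hoxa9 passed in 8 settings, for example at -0.34 without RAS-ON replicate 2 (adjusted p = 0.0039), and its adjusted p ranged from 0.000954 to 0.738. Low signal over background limits what can be said of dim genes such as Ddx4 and Il1bos.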

Other observations

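The genes and lists of this paragraph were chosen after their values were seen, and Gata1, Klf1 and Alas2 are also members of the erythroid list fixed earlier. Erythroid transcription factor genes were higher in RAS-OFF arrays, 10 of 10 by limma, with Gata1 up by 1.61 ± 0.05 (SE) on the log2 scale, Klf1 by 1.67 ± 0.13, Sox6 by 1.83 ± 0.12 and Gfi1b by 1.26 ± 0.08. All 7 measured haem synthesis genes rose, among them Alas2 by 1.39 ± 0.08 (SE) and Fech by 1.17 ± 0.06. The transferrin receptor gene Tfrc rose by 1.35 ± 0.08 (SE). Of 3 embryonic globin genes 2 rose, with a list median of 1.78, Hbb-bh1 by 1.78 ± 0.12 (SE). Globin family values are uncertain, as stated above for Hbb-y.

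Of 11 myeloid transcription factor genes, chosen in the same way, 10 fell and none rose, with a median of -0.57, and 7 had falling slopes. Cebpa fell by 1.48 ± 0.08 (SE) on the log2 scale, Spi1, which encodes PU.1, by 1.11 ± 0.13 and Irf8 by 0.57 ± 0.13. Cebpd had a change of 0.09 ± 0.07 (SE; adjusted p = 0.283) and a slope of -0.26 ± 0.03 (SE) per 12 h. Cdkn2a, a cell cycle inhibitor locus, fell by 2.22 ± 0.13 (SE). Of 8 eosinophil and basophil granule genes 3 rose and 1 fell, with a median of 0.04. Of 6 endocrine pancreas genes 3 fell, with a median of -0.12.

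The count of 8875 genes for RAS-OFF against RAS-ON was set against other assignments of the 15 arrays to groups of the same sizes, a test chosen after the count was seen. Of 100 splits 1, the real one, gave as many, and the highest of the others gave 2346. Random assignment of these arrays to groups thus did not reach the count. The splits treat the arrays as independent samples, which the labels do not state, so differences between a few animals or batches are not excluded.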
